A study of Arabidopsis thaliana with 32 samples.

How the data were processed

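RNA of inoculated and mock-treated Arabidopsis cell cultures was measured on 2-colour oligonucleotide arrays, with the culture's RNA in the Cy5 channel and a pool of RNA from mock-treated cultures in the Cy3 channel, per the labels. The dyes had the same orientation on all 32 arrays. Groups, times and replicate numbers were taken from the labels, which call the 4 replicates of each group biological. The values used are those of the deposited table, which holds 1 signed log ratio per spot and array for 26474 spots. The scanner, background correction, normalization and spot filters are not given in the sources used here. The values range from −5.66 to 6.59, which rules out log10 ratios from a 16-bit scanner, and the authors' deposited log ratios were taken as log2, since neither the base nor the numerator is stated. Scale and direction therefore remain unknown.

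In replicates 1 to 4 the array medians were −0.03, −0.04, −0.03 and −0.06 in inoculated cultures at 4 h. They were −0.01, −0.04, −0.03 and −0.02 at 12 h, −0.01, −0.01, −0.02 and −0.02 at 24 h and 0.01, 0.01, 0.06 and 0.00 at 48 h. In mock cultures they were −0.03, −0.03, −0.04 and −0.04 at 4 h, −0.03, −0.03, −0.02 and −0.04 at 12 h, −0.02, −0.04, −0.02 and −0.03 at 24 h and 0.01, 0.00, 0.00 and 0.00 at 48 h. The arrays were thus centred close to 0 before deposit, by a method that is not stated. SDs over probes ranged from 0.17 to 0.47 per array. Correlations between arrays ranged from −0.05 to 0.85.

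Control spots, 192 of 12 controls with 16 spots each, were left out of the comparisons, and the 17 spots of each of 12 repeated probes were averaged, which left 26090 probes. The median SD between spots of such a probe within an array was 0.11. The table has 0 missing values, so the minimum of 3 arrays per group removed nothing. Genes were taken from the platform annotation and their symbols updated through gene identifiers to the TAIR10.1 gene table. Of 4351 probes with 1 gene, 4333 matched, and they stand for 4108 genes, 165 of them with more than 1 probe. A probe with several genes was not named, and a probe without a listed gene is unnamed here. No coordinates are given because the build behind the array is not named.

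Differences were tested with limma 3.58.1 in R 4.3.3. One fit over all 32 arrays had 1 mean per group and 24 residual degrees of freedom, with empirical Bayes moderation and two-sided tests. It took the spread of a probe as equal in all groups. P-values were adjusted by Benjamini-Hochberg over the 26090 probes, with a threshold of 0.05. Contrasts were inoculated against mock at each time, the effect at 48 h against that at 24 h, a moderated F-test of the effect across the 4 times, and 48 h against 4 h within mock and within inoculated cultures. Gene lists with at least 5 probes were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over the lists at that time. The 23 lists fixed in advance hold 483 genes, of which 34 have a probe of their own, so that 1 list could be tested. For that reason 12 gene families were added after the tables of genes were seen and before any comparison was computed, and 11 of them were large enough. They were built from gene names or locus lists and adjusted among themselves. The medians of the ribosomal protein and glutathione transferase families, and of no other family, had exact permutation tests over the 35 splits of 8 arrays. These tests take no account of the replicate numbers and were not adjusted over the families.

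Named genes followed a rule set before the data were examined. For inoculated against mock it took up to 12 genes each way with the largest differences, among called single-gene probes with all 4 inoculated values beyond all mock values. In the other contrasts it took up to 5 each way with the largest differences among called single-gene probes, without the condition on overlap. It also took up to 4 members with the smallest p from each preset list. A gene with several probes was represented by the probe that comes first in the table.

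Replicate numbers were shared by all groups. Deviations from the group means of same-numbered inoculated and mock arrays correlated over probes between 0.33 and 0.71, and those of same-numbered arrays at 4 and 48 h between 0.12 and 0.40. All 8 arrays of each of the 6 comparisons correlated best with the array of their own number, so the numbers pair the samples, as seen from the data, since the labels do not say what a number stands for. The fit with the replicate number as a fixed block is therefore printed beside calls and counts that it changes. Unless the block is named, the SEs, adjusted p-values and fits with 1 array left out take no account of the pairs.

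Alternatives were centring each array on its median, quantile normalization of the log ratios, array weights, a trended and robust prior, the replicate block, a minimum of 2-fold, only the arrays of a contrast, and leaving out each array of a contrast in turn. The comparison and the family test were tested on simulated data. For the 48 h comparison, 50 of 26090 simulated probes were changed at each of 4 sizes, and 62% of the log2 differences of 0.5, 96% of those of 1, 100% of those of 1.5 and 96% of those of 2 were recovered, with 6 false calls among 25890 unchanged probes. These simulated arrays had independent noise and no replicate pairs.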

Results

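The series followed Arabidopsis thaliana cell cultures after contact with Agrobacterium tumefaciens, the soil bacterium that transfers DNA into plant cells. Total RNA was taken 4, 12, 24 and 48 h after inoculation from inoculated cultures and from mock-treated cultures. Each of the 8 combinations of treatment and time had 4 biological replicates, which made 32 arrays. Every array carried the culture's RNA labelled with Cy5 and a common reference, a pool of RNA from mock-treated cultures, labelled with Cy3. The deposited value of a spot is a log ratio between the 2 channels, taken here as log2. After spots of the same probe were averaged, 26090 probes were compared. Array medians lay between −0.06 and 0.06, and the median residual SD between arrays of a group was 0.15. Arrays give no counting depth, and the 4 arrays per group limit the precision of each value. Of the probes, 4351 are assigned to 1 gene in the annotation, 3479 to several genes and 18260 to none, so most of the probes counted below have no name here.

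The direction of the ratios is not settled. The labels give the dyes but not which channel is the numerator, and the values themselves did not decide it. Signed values are therefore those of the deposited ratio, read in channel order as culture over reference. Read as reference over culture, every direction below turns round, while sizes, errors, counts and the opposition between gene groups stay as they are. The direction of the study as it is known from outside these data opposes the channel-order reading. A fold is 2 raised to the size of the difference. The log base is not stated either, and log2 differences would be 1.44 times as large if the values were natural logs.

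The question of the series was what inoculation changes at each time. At 48 h the largest separations from mock had lower deposited ratios in inoculated cultures. The class III peroxidase gene AT5G39580 averaged −1.74 ± 0.68 (SD, n = 4 arrays) in inoculated and 0.21 ± 0.56 in mock cultures, a difference of −1.95 (SE 0.38), or 3.87-fold. A further probe of AT5G39580 gave −1.22 (SE 0.22). AT5G24760, which encodes a protein of the alcohol dehydrogenase family, averaged −2.58 ± 0.53 against −0.66 ± 0.14, a difference of −1.92 (SE 0.21). The peroxidase gene AT5G64120 (PRX71) differed by −1.89 (SE 0.34). The limma adjusted p-values of these genes were 0.0048, 1.4e-06 and 0.0023, and all 4 same-numbered pairs had the same direction for each, as the choice of genes with separate groups required. Smaller differences of the same sign were found for AT1G65500 at −1.37 (SE 0.20), for the chaperonin subunit gene AT3G03960 at −1.02 (SE 0.19), for AT1G52200 at −0.99 (SE 0.15), for AT3G44780 at −0.95 (SE 0.14) and for AT1G61660, a basic helix-loop-helix transcription factor gene, at −0.88 (SE 0.15). GSTU22, a tau-class glutathione transferase gene, differed by −0.84 (SE 0.17), AT1G72600 by −0.84 (SE 0.14), the leucine-rich repeat receptor kinase gene AT1G51810 by −0.83 (SE 0.21) and UGT72E1, a glucosyltransferase gene acting on lignin precursors, by −0.80 (SE 0.14). The call of AT1G51810 was lost without inoculated replicate 2, 3 or 4 or mock replicate 1, 2 or 4, at adjusted p-values from 0.053 to 0.093.

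Higher deposited ratios in inoculated cultures at 48 h were smaller in size and included several genes of protein synthesis. LCR69, of the plant defensin family, averaged 0.07 ± 0.35 in inoculated and −0.95 ± 0.17 in mock cultures (SD, n = 4 arrays each), a difference of 1.01 (SE 0.21), or 2.02-fold. AT3G08030 differed by 0.92 (SE 0.22), SAH7 by 0.83 (SE 0.13) and AT2G46890 by 0.73 (SE 0.13). The 4 ribosomal protein genes among the named genes were AT1G41880 at 0.72 (SE 0.15), AT3G06700 at 0.65 (SE 0.14), AT3G16780 at 0.64 (SE 0.12) and AT5G28060 at 0.58 (SE 0.15). AT5G27120, which encodes a nucleolar protein of the type that acts in ribosomal RNA modification, differed by 0.70 (SE 0.17). The remaining named genes were the protein kinase gene AT2G44830 at 0.65 (SE 0.12), the remorin gene AT2G45820 at 0.63 (SE 0.12) and the patellin gene AT1G30690 at 0.57 (SE 0.13). The limma adjusted p-values of these 12 genes lay between 0.00066 for SAH7 and 0.037 for AT5G28060. The call of AT1G30690 was lost with quantile normalization, at a difference of 0.46 and an adjusted p of 0.10, and that of AT1G41880 at 0.76 and 0.055. With 1 array left out, the call of AT5G28060 was lost without inoculated replicate 3 or 4 or any of the 4 mock replicates (adjusted p from 0.059 to 0.14), and that of AT5G27120 without inoculated replicate 3 or 4 or mock replicate 1, 2 or 4 (0.050 to 0.11). The call of AT1G30690 was lost without inoculated replicate 3 or mock replicate 2 or 4 (0.055 to 0.12) and that of AT3G08030 without inoculated or mock replicate 3 (0.052 and 0.076). AT1G41880 did not pass without inoculated replicate 3 (0.056), nor AT3G06700 without inoculated replicate 4 (0.056).

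**Figure D1:**
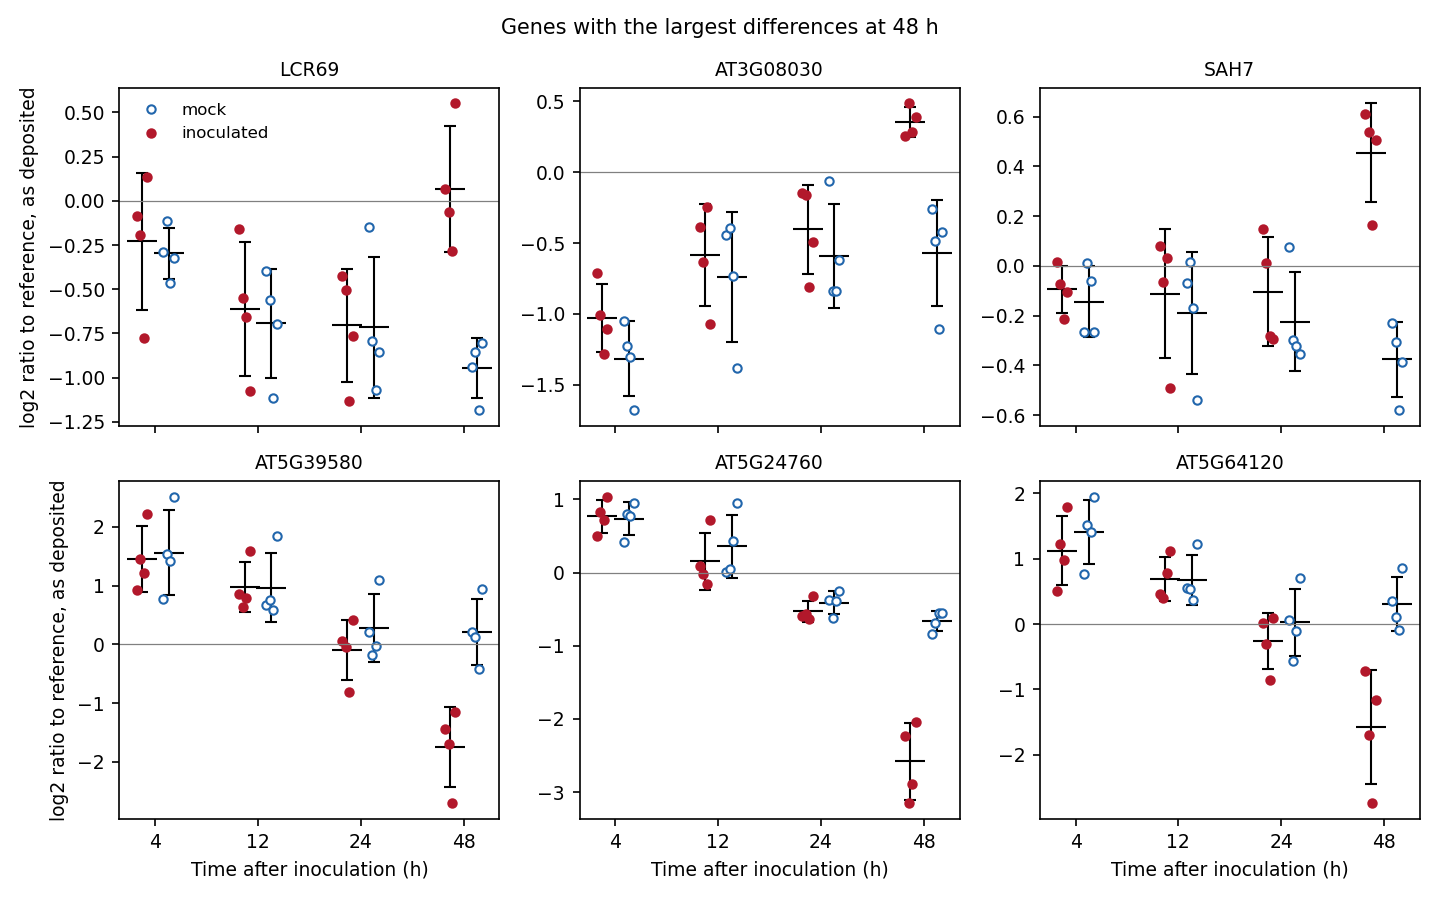
Deposited log2 ratio to the reference (vertical axis) against time after inoculation in h (horizontal axis) for the 3 genes with the largest positive and the 3 with the largest negative difference at 48 h. Filled red points are inoculated and open blue points are mock arrays, 4 per group; horizontal bars are means and error bars are SDs. The genes were chosen among those whose inoculated and mock values do not overlap at 48 h, where the means of AT5G24760 are −2.58 and −0.66.

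In all, 451 of the 26090 probes (1.73%) passed an adjusted p of 0.05 at 48 h in limma, 205 with a higher and 246 with a lower deposited ratio in inoculated cultures. The median size of their difference was 0.51. A difference of at least 2-fold was found for 47 of them, 2 higher and 45 lower. The count was 1644 with the replicate number as a block, which included all 451, and 7 when only the 8 arrays of this comparison entered the fit. Which side held more calls depended on the setting, with 928 higher and 716 lower under the replicate block, 266 and 245 without inoculated replicate 2 and 179 and 177 without mock replicate 1, but 163 and 288 with each array centred on its median, 246 and 470 without inoculated replicate 1 and 141 and 335 without mock replicate 3. The count also moved to 716 without inoculated replicate 1, to 223 without inoculated replicate 3, to 295 without mock replicate 2 and to 205 without mock replicate 4. Of the 451 probes, 80 have 1 gene, 45 have several genes, 324 have no gene listed and 2 have a gene that matched no current locus. Among the single-gene probes, 65 represented a gene, passed the test and had all 4 inoculated values beyond all 4 mock values, and the 24 genes above have the largest differences of these. Over all 26090 probes, called or not, 1587 (6.08%) had such separate groups, where chance gives 2.86% for a probe not chosen by its test. For 7 genes with several probes at least 1 probe was called. All probes had the same sign in 4 of the 7, and AT5G39580 was the one gene of these with all its probes called. Over all 165 genes with several probes, called or not, the probes agreed in sign in 76. AT5G19440 had probes at −0.93 (SE 0.18, limma adjusted p = 0.0043) and 0.24 (SE 0.09, limma adjusted p = 0.23), and the latter, not called, represented the gene.

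Gene families formed from the annotation, after the tables of genes but before any comparison was seen, showed 2 opposite shifts at 48 h. Of the 60 probes of cytosolic ribosomal protein genes, 9 had a higher ratio in inoculated cultures, none had a lower one, and 51 did not pass the test. Their median difference was 0.30, or 1.23-fold, with 55 of 60 values above 0. Beside the genes named above, the 9 included AT1G18540 at 0.46 (SE 0.10) and AT2G37190 at 0.48 (SE 0.12). Adjusted over the list alone, 30 probes had a higher ratio, and with the replicate block 23 did. The family stood apart from the other probes in camera, at an adjusted p of 6.3e-20, and at an adjusted p of 0.039 with an estimated correlation. With the replicate block and an estimated correlation the adjusted p was 0.11, and the call was lost. No other of the 35 splits of the 8 arrays gave a median as large, which is an exact permutation p of 0.0286, two-sided, the smallest that 4 arrays against 4 can give. This p was not adjusted over the families. The 35 splits take no account of the same-numbered pairs, and those that keep pairs apart are too few for a share under 0.05. The median was above 0 in each of the 4 same-numbered pairs, between 0.22 and 0.37.

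The glutathione transferases had the opposite sign. Of 8 probes, 3 had a lower ratio in inoculated cultures, none had a higher one and 5 did not pass the test. These 3 were GSTU26 at −0.55 (SE 0.09), GSTU22 at −0.84 (SE 0.17) and GSTU23 at −0.64 (SE 0.15), and GSTF4, at −0.37 (SE 0.11), did not pass. Adjusted over the list alone, 4 had a lower ratio. The median was −0.33, or −0.21 with quantile normalization, with all 8 values below 0, and the camera adjusted p was 1.7e-07, or 0.00011 with an estimated correlation. The exact permutation p of the median was 0.0286, two-sided, over all 35 splits, and was not adjusted over the families. These splits take no account of the same-numbered pairs. The 8 splits that keep pairs apart are too few for a share under 0.05, although none of the others gave a median as large in size. Among the 18 UDP-glycosyltransferase probes, UGT72E1 and UGT76B1, the latter at −0.34 (SE 0.07), had a lower ratio and the other 16 did not pass. The family median was −0.07, with a camera adjusted p of 0.011 and 0.026 with an estimated correlation. Adjusted over the list alone, 4 UDP-glycosyltransferase probes had a lower and 1 a higher ratio. Of 5 peroxidase probes, which include 3 of the organellar ascorbate peroxidases SAPX and TAPX, AT5G64120 was the one called. The family was formed from gene names and does not hold AT5G39580. Its median was −0.19, and −0.03 with quantile normalization. The camera adjusted p of the peroxidases was 0.011, but their adjusted p with an estimated correlation was 0.084. All 7 tubulin probes had values above 0, none passed the test, and the camera adjusted p of 0.11 did not pass, although it was 0.040 with the replicate block.

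**Figure D2:**
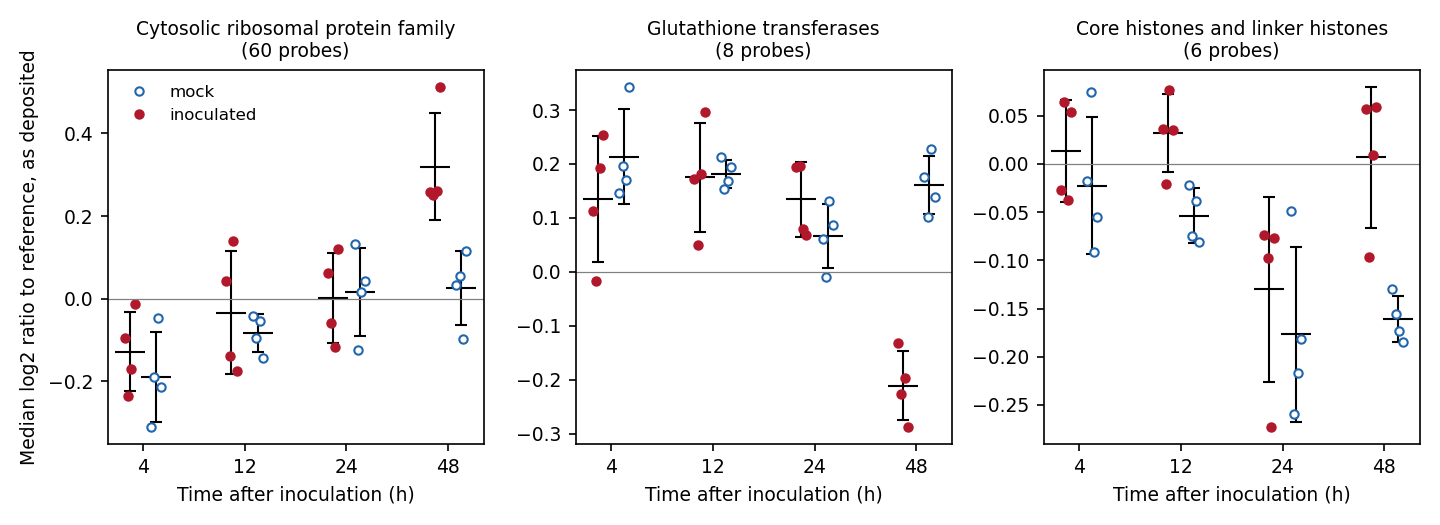
Median deposited log2 ratio over the probes of a family on each array (vertical axis) against time after inoculation in h (horizontal axis) for 60 ribosomal protein, 8 glutathione transferase and 6 histone probes. Filled red points are inoculated and open blue points are mock arrays, 4 per group, with bars at the mean and SD; at 48 h the ribosomal medians averaged 0.32 ± 0.13 in inoculated and 0.03 ± 0.09 in mock cultures.

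Of the 23 gene lists fixed before the data were examined, 1 had enough probes of its own for a test. In that list of core and linker histones, which package DNA, none of the 6 probes passed the test at 48 h, over all probes or adjusted over the list alone. The median difference was 0.25, with 5 of 6 values above 0, and the camera adjusted p was 0.049. The call was not kept with an estimated correlation, at an adjusted p of 0.055, nor without inoculated replicate 1 or 4 or mock replicate 2, 3 or 4, at adjusted p-values from 0.058 to 0.17. The alternatives run with camera for this list were centring, quantile normalization, the replicate block, an estimated correlation and 1 array left out. Over these its adjusted p ranged from 0.025 to 0.17. The fry test, which sets the list against no change and not against the other probes, gave an adjusted p of 0.0053. Examples are HTB2, a histone H2B gene, at 0.31 (SE 0.12), and the linker histone genes AT2G30620 at 0.29 (SE 0.11) and HIS1-3 at −0.24 (SE 0.16).

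The other preset lists could be described gene by gene. In 7 of them, those of salicylic acid, jasmonate, camalexin and indole glucosinolates, cyclins and mitosis, cell wall expansion, phosphate starvation and tracheary elements, no gene had a probe of its own. The other 15 lists held 32 probes, of which GSTU22 was the one called at 48 h. Adjusted over the list alone, GSTU22, STZ and RR16 had a lower ratio, and of the reference genes 1 probe had a higher and 1 a lower ratio. In the early immune list, STZ, a zinc-finger repressor gene of stress responses, differed by −0.44 (SE 0.17, limma adjusted p = 0.22), with an adjusted p of 0.043 under the replicate block. WRKY6 differed by −0.24 (SE 0.17) and WRKY22 by −0.03 (SE 0.08). RR16, a response regulator gene of cytokinin signalling, differed by −0.42 (SE 0.15, limma adjusted p = 0.18), with an adjusted p of 0.040 under the replicate block. In the auxin list, none of LBD16 at −0.23 (SE 0.11), GH3.3 at 0.19 (SE 0.21), GH3.1 at −0.24 (SE 0.31) and IAA29 at 0.07 (SE 0.09) passed. The short preset ribosomal list held AT1G70600 at 0.29 (SE 0.12), with a further probe at −0.018 (SE 0.08), and AT2G31610 at 0.32 (SE 0.15). Among genes known to affect transformation by the bacterium, ATLIG4, a DNA ligase gene, differed by −0.04 (SE 0.12) and MYBC1 by −0.03 (SE 0.16). The remaining lists gave 0.35 (SE 0.24) for the lignin gene CCR2, −0.20 (SE 0.10) for GSTU20, 0.18 (SE 0.11) for the replication gene PRL, −0.0020 (SE 0.10) for EIN3 of ethylene signalling, 0.19 (SE 0.15) and −0.42 (SE 0.33) for the 2 probes of LHCB4.1 and 0.02 (SE 0.21) for PSAE-1 of photosynthesis. They also gave 0.10 (SE 0.11) for MCCA and 0.04 (SE 0.17) for IVD of amino acid breakdown, 0.12 (SE 0.33) for the low-oxygen gene AT3G10040, −0.47 (SE 0.32) and −0.015 (SE 0.17) for the 2 probes of the heat shock gene ATHSP22.0, −0.0026 (SE 0.09) for AT1G53540, −0.25 (SE 0.12) for SAG29 and 0.16 (SE 0.18) for GAMMA-VPE of senescence and cell death. Of the reference genes, AT5G60390, a translation elongation factor gene, differed by 0.34 (SE 0.14), and the 2 probes of AT2G28390 by −0.24 (SE 0.10) and 0.02 (SE 0.07).

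At 4, 12 and 24 h no probe passed an adjusted p of 0.05 in limma, with or without the replicate block. The block gave each replicate number 1 shift shared by all times, and a fit with the pairs of each time was not run. At an unadjusted p under 0.05 in the fit without the block there were 551 probes at 4 h, 467 at 12 h and 290 at 24 h. Without any effect, 1304 of 26090 would be expected on average. These counts lie far below that number, so the 0 calls do not show that no probe changed. AT5G24760 differed by −0.12 (SE 0.21) at 24 h, AT5G39580 by −0.37 (SE 0.38) and AT5G64120 by −0.29 (SE 0.34). LCR69 differed by 0.01 (SE 0.21) and AT3G08030 by 0.19 (SE 0.22). The ribosomal protein family had median differences of 0.06 at 4 h, 0.08 at 12 h and −0.01 at 24 h. Its camera adjusted p was 0.0011 at 4 h and 0.0023 at 12 h, but the adjusted p with an estimated correlation was 0.92 and 0.99, and the same-numbered pairs went both ways at each of these times. The glutathione transferase medians were −0.06, 0.01 and −0.03. In simulated data of the same size, with 50 probes changed at each size in the 48 h comparison, 62% of differences of 0.5 and 96% of differences of 1 were recovered. Those arrays had independent noise, no replicate pairs and no change at the earlier times. The shares recovered therefore do not carry over to 4, 12 and 24 h.

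Whether the effect of inoculation changed between 24 and 48 h was tested directly. For AT5G24760 the effect at 48 h was lower than that at 24 h by −1.80 (SE 0.29, limma adjusted p = 0.0039), and for AT3G44780 by −1.04 (SE 0.20, limma adjusted p = 0.031). For the peroxidase genes AT5G39580 and AT5G64120 the differences of −1.58 (SE 0.54) and −1.60 (SE 0.48) did not pass, at adjusted p-values of 0.61 and 0.46, but they passed with the replicate block, at 0.0080 and 0.0498. The 24 genes named at 48 h were chosen by their differences at 48 h, which enter this test and so favour passing. Of these genes 2 passed without and 11 with the block, where 20 and 75 of all 26090 probes did. The others that passed with the block alone were LCR69 (0.0498), SAH7 (0.030), AT3G16780 (0.0014), AT1G65500 (0.023), AT3G03960 (0.018), AT1G52200 (0.023) and UGT72E1 (0.048). Neither of these 2 calls held with quantile normalization, where the differences were −1.05 and −0.73 and the adjusted p-values 0.62 and 0.25. The call of AT3G44780 was also lost without inoculated replicate 1, 2 or 4 or mock replicate 2, 3 or 4 of 24 h, and without inoculated replicate 3 or mock replicate 1, 2 or 4 of 48 h, at adjusted p-values from 0.052 to 0.11. In all, 20 probes passed, 2 of them higher and 18 lower at 48 h. The count was 75 with the replicate block, 9 with quantile normalization, 47 with array weights and 4 when only the 16 arrays of these groups entered the fit. It moved to 57 without inoculated replicate 1 of 48 h, 34 without inoculated replicate 4 of 48 h, 11 without inoculated replicate 2 or mock replicate 1 of 24 h, 12 without mock replicate 2 of 24 h and 13 without mock replicate 4 of 48 h. The F-test across the 4 times also called 20 probes, among them AT5G24760, AT3G44780 and AT1G65500, and it called 70 with the replicate block, 12 with quantile normalization, 44 with array weights and 65 without inoculated replicate 1 of 48 h. The ribosomal protein family passed the test of 48 h against 24 h as a whole, with a median of 0.30, a camera adjusted p of 1.4e-20 and an adjusted p of 0.041 with an estimated correlation, which was 0.094 with the replicate block as well. The glutathione transferases had a median of −0.28, with adjusted p-values of 2.7e-07 and 0.00013 in the same tests.

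The cultures were also compared with themselves over time, without and with bacteria. In mock cultures, between 4 and 48 h the ratio of the peroxidase gene AT3G21770 went from 1.00 ± 0.44 to −0.98 ± 0.33 (SD, n = 4 arrays each), a difference of −1.98 (SE 0.17, limma adjusted p = 1.3e-07). The metallothionein gene MT1C differed by −1.86 (SE 0.24), the UDP-glycosyltransferase gene AT2G22590 by −1.76 (SE 0.32), AT1G62050 by −2.10 (SE 0.47) and AT2G03250 by −1.88 (SE 0.40). Higher ratios at 48 h were found for AT4G27450 at 2.33 (SE 0.71), AT5G11420 at 1.07 (SE 0.30), the expansin gene EXPB3 at 1.05 (SE 0.29), AT1G48570 at 0.76 (SE 0.08) and AT3G08030 at 0.75 (SE 0.22). The call of AT4G27450 was lost with array weights, at a difference of 1.51 and an adjusted p of 0.071, and without any 1 of the 4 h replicates or replicate 3 or 4 of 48 h (0.061 to 0.16). That of AT5G11420 was lost without replicate 2, 3 or 4 of 4 h or 1 or 3 of 48 h (0.050 to 0.097), that of EXPB3 without replicate 3 or 4 of 4 h or 1 or 2 of 48 h (0.060 to 0.13), and that of AT3G08030 without replicate 2, 3 or 4 of 4 h or 1, 2 or 4 of 48 h (0.060 to 0.13). In all 1886 probes passed, 857 higher and 1029 lower, and 4301 with the replicate block. The split was 556 higher and 1262 lower when each array was centred on its median, and 579 and 1196 with quantile normalization, but 2330 higher and 1971 lower with the replicate block and 2654 and 1926 with array weights, so the side with more calls depended on the setting. At least 2-fold were 14 higher and 191 lower. The count was 986 with only the 8 arrays of the comparison, 4580 with array weights, 1124 without mock replicate 2 of 4 h, 1018 without mock replicate 4 of 4 h and 1054 without mock replicate 3 of 48 h. Of the ribosomal protein probes 13 had a higher ratio at 48 h than at 4 h and none a lower one, with a family median of 0.22. The camera adjusted p of that family was 2.9e-09, but it was 0.38 with an estimated correlation.

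In inoculated cultures AT5G24760 went, between 4 and 48 h, from 0.77 ± 0.23 to −2.58 ± 0.53 (SD, n = 4 arrays each), a difference of −3.35 (SE 0.21) or 10.2-fold, with a limma adjusted p of 2.4e-11. The peroxidase genes AT5G39580 and AT5G64120 differed by −3.20 (SE 0.38) and −2.70 (SE 0.34), MT1C by −2.54 (SE 0.24) and AT1G22910 by −2.30 (SE 0.37). Higher ratios at 48 h were found for AT4G27450 at 2.25 (SE 0.71), AT3G08030 at 1.38 (SE 0.22), AT5G11420 at 1.18 (SE 0.30), the ribosomal protein gene AT1G27400 at 1.15 (SE 0.17) and the glycosyl hydrolase gene GH9C2 at 1.09 (SE 0.33). The call of AT4G27450 was lost with array weights (adjusted p = 0.069) and without replicate 1 or 2 of 4 h or 3 or 4 of 48 h (0.052 to 0.11), and that of GH9C2 without replicate 4 of 4 h (0.084) or 1 of 48 h (0.054). In all 6056 probes passed, 3727 higher and 2329 lower. The split was 2272 higher and 3121 lower with each array centred on its median and 2079 and 2311 with quantile normalization, so which side held more calls depended on the scaling. At least 2-fold were 36 higher and 442 lower. With the replicate block 9206 probes passed, and with only the 8 arrays of the comparison 2650. Of the 60 ribosomal protein probes 44 had a higher ratio at 48 h and none a lower one, with a family median of 0.47, a camera adjusted p of 5.6e-17 and an adjusted p of 0.048 with an estimated correlation, which was 0.13 with the replicate block as well. Of the 8 glutathione transferase probes 5 had a lower and none a higher ratio. The mock and inoculated changes had a Pearson correlation of 0.82 over probes, which are not independent replicates. They share no array but are not independent of each other, because same-numbered inoculated and mock arrays deviated together. Both changes passed for 1489 probes, 1486 of them in the same direction.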

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

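The test of the added gene families over the other splits was not planned. Neither were the comparisons with splits or regroupings that keep same-numbered pairs apart, nor the processing alternatives for the ribosomal protein family. All of these count as chosen after the result was seen. Of 127 groups of 4 arrays examined, 7 had 1 array far from the other 3, and chance gives about 1 in 20, or 6.35. The distance is the gap to the nearest array as a share of the group's range. In mock cultures at 48 h, replicate 3 was lowest for AT1G65500 (−0.32, share 0.839), AT3G44780 (−0.30, share 0.856) and GSTU22 (0.19, share 0.856). Replicate 1 was highest for AT3G44780 in mock cultures at 24 h (share 0.876) and lowest for AT3G21770 in mock cultures at 4 h (share 0.841). Replicate 3 had the lowest histone median in inoculated cultures at 24 h (share 0.876). Replicate 4 had the highest ribosomal protein median in inoculated cultures at 48 h, 0.51 against 0.26 for the next (share 0.964).

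The effect of inoculation differed between 24 and 48 h for 20 probes and across the 4 times for 20 probes. AT5G24760 changed by −1.80 and AT3G44780 by −1.04 between these times, and AT1G65500 had an adjusted p of 0.047 in the F-test. In 100 regroupings within each time, the real one included, 6 called at least as many probes as the real one between 24 and 48 h, up to 698. In the F-test 8 of 100 did, up to 399. Chance is therefore not excluded for either count, and counts that high point to a structure of the samples. The drawn regroupings that kept all 8 same-numbered pairs apart, 6 in number, called at most 13 probes between 24 and 48 h. The control spots, which entered no comparison, gave no call for any of the 12 controls at any time, with differences between −0.11 and 0.19.

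The first pattern weighed is the number of probes that differ at 48 h: of the 35 splits of the 8 arrays, 3 called at least 451, so chance is not excluded over all splits. The highest other split called 996 and set inoculated replicate 1 with mock replicates 1, 2 and 4 against the rest, and another called 713 and set replicates 1 and 2 against 3 and 4, so the replicate numbers carry a structure as large as the effect. Among the 8 splits that keep every pair apart the real one called 451 and the others 0, and with the replicate block 1644 against at most 1, but 8 splits are too few for a share under 0.05. A further advance of inoculated cultures along the change that mock cultures make with time may account for part of it, but the correlation over probes of the difference at 48 h with the mock change from 4 to 24 h, which shares no array with it (r = 0.16, with 310 of the 451 probes of the same sign), was matched in size, the sign of another split being arbitrary, by 9 of the 35 splits, up to 0.23, and by 2 of the 8 that keep pairs apart, the real one included in both and the other of the 8 at 0.19. A share of at least 0.05 over the 35 splits had been set beforehand as counting against this explanation, and 9 of 35 is such a share. The rule was set aside only after the result was seen. The 35 splits take no account of the pairs, and the 8 that keep pairs apart cannot give a share under 0.05. A correlation above 0 is also not a value the explanation forbids, so this explanation cannot be told apart from a direct effect of the bacteria.

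The second pattern is the shift of the ribosomal protein family at 48 h. A scaling or shape difference between arrays is argued against by the median of 0.25 after quantile normalization, which still passed its test, and a single replicate by the lowest of the 4 pair medians, 0.22, and by 0.23, the lowest median with any 1 array left out. A bias of bright spots cannot be told apart from a change in these genes, because the 3 reference gene probes went both ways, so their median of 0.021, below the 0.15 set beforehand as the bound against this, decides nothing. With 4 families called, 4 of the 35 splits called at least as many, up to 5, so chance is not excluded for the number of families, while no other split gave a ribosomal median as large, those that keep pairs apart included, although these 8 splits are too few for a share under 0.05. An effect of inoculation stays open as a hypothesis.

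The third pattern is the sign of the ratios. If the values are culture over reference and the reference pools the mock samples evenly, probes that change over time in mock cultures would have lower mean values the larger the gap between their log mean and mean log, and the reverse for reference over culture. Over 2073 such probes the slope was −0.62, but the slopes of the 4 replicates were 0.15, 0.29, −2.41 and −0.49, with an SD of 1.24. The 2 readings therefore cannot be told apart from these values. No biological explanation was tested for the sign.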

How the results depend on the processing

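The added families were formed after the tables of genes were seen and before any comparison was computed; their alternatives were chosen after seeing the data. No value was missing, so the filters on missing values were not run. The counts of 0 at 4, 12 and 24 h held under every alternative run. For 48 h the count of 451 was 1644 with the replicate block, 47 at 2-fold and 7 with only the arrays compared, and 205 to 716 with 1 array left out. The effect at 48 h against 24 h (20) gave 9 with quantile normalization, 47 with array weights, 75 with the replicate block, 4 with only the arrays compared and 11 to 57 with 1 array left out. The F-test (20) gave 12, 44 and 70 in the first 3 of these and 16 to 65. Mock cultures at 48 h against 4 h (1886) gave 4580 with array weights, 4301 with the replicate block, 205 at 2-fold, 986 with only the arrays compared and 1018 to 2105 with 1 array left out. Inoculated cultures (6056) gave 9206, 478 and 2650 with the block, at 2-fold and with only their arrays, and 4131 to 6005. Fewer arrays leave fewer degrees of freedom, and the 2-fold minimum can only remove calls. The fit over all arrays also takes the spread of a probe as equal in all groups, on which the printed SEs rest. At 48 h the SDs in inoculated and mock cultures were 0.79 and 0.12 for AT1G65500 and 0.55 and 0.11 for AT1G72600. For AT3G08030 they were 0.10 and 0.37, the other way round. How much of the drop with fewer arrays comes from either was not tested, nor was the cause for the other settings. The number of preset lists called went from 1 to 0 at 48 h with an estimated correlation and ranged from 0 to 1 with 1 array left out at 48 h and at 12 h, where it was 1 without inoculated replicate 1. The 4 added families called were 3 with an estimated correlation and 5 with the block. The ribosomal median of 0.30 lay between 0.23 and 0.33 with 1 array left out, and lost its call with the block and an estimated correlation together.

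Of 46 called differences of named genes, none changed sign with centring, quantile normalization, array weights, the block or 1 array left out, and 31 kept their call in all of these. The block ended no call of these genes and moved STZ and RR16 past the threshold. For AT5G39580 at 48 h it took the SE from 0.38 to 0.20 and the limma adjusted p from 0.0048 to 6.9e-07. For AT1G48570 in mock cultures, 48 h against 4 h, the SE stayed at 0.077. The fits with 1 array left out were not run with the block, so whether the calls lost there would be lost with it is unknown. The trended and robust prior, the 2-fold minimum and the fits with only the arrays of a contrast were run for counts alone. At 48 h the last of these left few calls of any probe, so the calls of named genes cannot be taken to hold there. Of 35 differences not called, 12 near 0 changed sign. The values were −0.036 for IVD and −0.012 for AT2G28390 with quantile normalization, and 0.0028 for WRKY22, 0.037 for AT1G70600, 0.037 for MYBC1, 0.0027 for AT1G53540 and −0.012 for AT2G28390 with array weights. With 1 array left out they ranged from −0.072 to 0.043 for EIN3, −0.15 to 0.078 for ATLIG4, −0.091 to 0.049 for MYBC1, −0.13 to 0.13 for ATHSP22.0, −0.033 to 0.036 for AT1G53540, −0.078 to 0.018 for AT1G70600, −0.017 to 0.14 for IAA29, −0.10 to 0.17 for IVD, −0.021 to 0.068 for AT2G28390, −0.066 to 0.022 for WRKY22, −0.24 to 0.19 for PSAE-1 and −0.093 to 0.32 for AT3G10040. Signal over background is not in the deposited values, so dim spots could not be set apart.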

Other observations

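The comparisons with splits that keep same-numbered arrays apart were not planned and count as chosen after the result was seen. The signs of the probes called at 48 h were compared with their signs at earlier times, where none of them passed a test. Of the 451 probes, 336 (74.5%) had the same sign at 24 h, 259 (57.4%) at 12 h and 327 (72.5%) at 4 h. Their median difference in the direction of 48 h was 0.04 at 24 h, 0.02 at 12 h and 0.05 at 4 h, against 0.51 at 48 h. Over all probes the effect at 48 h had a Pearson correlation of 0.19 with that at 4 h, 0.05 with that at 12 h and 0.29 with that at 24 h. Among the earlier times the correlations were 0.15 for 4 and 12 h, 0.07 for 4 and 24 h and −0.04 for 12 and 24 h. These correlations are over probes, which are not independent replicates. None of these comparisons shares an array with another, but same-numbered arrays of a treatment at 4 and 48 h deviated together. The shares and correlations that would arise without an effect were not computed.

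The added families of Aux/IAA and GH3 genes, expansins and xyloglucan endotransglucosylases, thioredoxins and glutaredoxins, cytochromes P450, AGAMOUS-like genes and low-molecular-weight cysteine-rich genes did not pass camera at 48 h, with adjusted p-values of 0.63, 0.36, 0.84, 0.41, 0.84 and 0.41 and medians of −0.03, −0.03, 0.04, −0.09, −0.01 and 0.03. The last of these medians was −0.02 with quantile normalization. The thioredoxins and the AGAMOUS-like genes had means of the other sign, −0.05 and 0.0038. LCR69 was the one called member of these families. Late embryogenesis abundant genes had 4 probes, too few for the test, all above 0 at 48 h with a median of 0.12. Among them LEA18 differed by 0.26 (SE 0.08, adjusted p = 0.083) and passed when adjusted over the list alone.

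In the comparisons at 4, 12 and 24 h no probe was called. Every split gives a count of at least 0, so the 35 splits cannot test these results. They called up to 6 probes at 4 h and 0 at 12 and 24 h. The same limit holds for the preset lists, with a real count of 0 lists at these times. There the splits called at most 0, 1 and 1 lists at 4, 12 and 24 h. At 48 h, 4 of the 35 splits called the histone list as the real one did, so chance is not excluded for it. For 48 h against 4 h, 1 of 35 splits, the real one, gave as many calls in mock cultures (1886, highest other 7). The same was found in inoculated cultures (6056, highest other 955). These shares are under 0.05, but the 35 splits take no account of the shared replicate numbers. The 8 splits that keep same-numbered arrays apart are too few for a share under 0.05, so chance is not excluded. Among these the real one called 1886 against 0 in mock cultures, or 4301 against at most 283 with the replicate block. In inoculated cultures it called 6056 against at most 440, or 9206 against at most 3405 with the block.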
